A study of Homo sapiens with 6 samples.

How the data were processed

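The study holds 6 one-colour arrays of PC-346C cells, 3 with vehicle and 3 with 50 µM Casodex, harvested after 48 h. Groups and replicate numbers came from the sample titles. The title, source name and treatment protocol put the Casodex samples in their group, while their description field carries the vehicle text, so the titles were followed. The labels' protocols give 36 h between plating and treatment in one place and 24 h in another. Cells were plated in 150 cm2 dishes in 25 mL of medium with 2% charcoal-stripped serum, and the carrier was 75% ethanol and 25% DMSO, per the labels. The medium is described for both groups alike.

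Hybridisation and first processing were done by the array's maker, per the series' design text. RMA is named in the submitters' processing notes, with no version. RMA corrects background, sets the intensity distributions of all arrays equal and summarises probes per transcript. The deposited sheet holds 1 intensity per transcript and array on a linear scale. It is titled as raw data, but its values showed the marks of this processing: medians of 281.1 to 292.05 and sorted values that differed by at most 0.24 on the log2 scale. The values were therefore taken as background-corrected and normalized by the authors, and no second normalization was applied. A normalization of this kind assumes that about as many genes rise as fall, so a general drop in RNA per cell would not be seen. Probe sequences, the array's design and genome build are not given in the sources used here.

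A second deposited table holds, for each transcript, the linear ratio of each array's value to that transcript's median over the 6 arrays. All 37870 of its row medians lay within 0.001 of 1, and 33910 rows (89.5%) matched a row of the sheet within 0.01 on the log2 scale. The column medians ran from 0.959 to 1.02, so the scale and centring are known and the direction is that of the sheet. Its row identifiers matched none of the sheet's, so it gave counts of rows only. No detection calls or background flags were used, and no batch, slide or scan date was available for a test. Values near the floor (minimum intensities of 20.9 to 22.4) compress fold changes.

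Symbols were assigned through the RefSeq accession of each row, in a gene table of the GRCh38.p14 assembly used for names only. Of 37870 rows, 16737 matched 1 current gene (16707 of 18775 curated transcripts and 0 of 19013 predicted models). For 14769 genes the row with the highest mean over all arrays was kept, which left 1968 other rows of the same genes unused, and 21133 rows stayed unnamed.

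Log2 intensities were fitted per gene with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), Casodex minus vehicle, with no covariate. Adjusted p-values are Benjamini-Hochberg values over 14769 genes, with a threshold of 0.05. Gene lists were tested two-sided with camera at a preset correlation of 0.01 and adjusted over the 23 lists. Adjustment over a list alone used only its members. The androgen response score was compared by an exact permutation test. The design had assumed that the sheet held unnormalized intensities or, if already summarised, would be used on the log2 scale, and the second case applied.

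Choices made before the data were examined were the groups, tests, lists, alternatives and the rule for named genes. The rule takes the 12 largest rises and 12 largest falls past the threshold with groups that do not overlap, up to 4 members of each list with the smallest p, and a fixed set that includes KLK3, KLK2, TMPRSS2, FKBP5, CDKN1A, MKI67, HMGCS1 and UGT2B17 in any case. It gave 102 genes, and results of some of them are not reported here. The lists held 647 entries, of which 628 were measured. They were androgen-induced and androgen-repressed genes, S phase, G2 phase and mitosis, p53 targets, pro-apoptotic genes, cholesterol synthesis, fatty acid synthesis, ER chaperones, ATF4, NRF2, AhR and PXR targets, steroid metabolism, glycolysis and hypoxia, oxidative phosphorylation, ribosome biogenesis, MAPK feedback, glucocorticoid-induced and interferon-stimulated genes, and neuroendocrine, luminal, basal, and stromal, endothelial and immune markers.

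The scripts were tested on simulated data with the real genes' means and spreads and 200 changed genes. The fit recovered 43.3% of 67 genes changed by 1 on the log2 scale, 89.6% of 67 changed by 2 and 95.5% of 66 changed by 3, with 8 false calls among 160. The simulated values had the same spread in every array and were independent between genes. They hold no outlying array like vehicle replicate 1, so these rates show that the scripts work and do not measure recovery in the real data. The list test recovered 4 of 4 moved lists and called 0 of 100 unmoved lists of independent genes. It therefore does not cover lists of correlated genes, and estimated correlations in the real lists reached 0.40 (G2 phase and mitosis).

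Alternatives were the ratio table, quantile, median and cyclic loess normalization, leaving out the dimmest 33.3% of genes, the mean of all rows per gene, eBayes without trend or robust, array weights, the replicate number as a block, leaving out each array, a 2-fold threshold, limma's treat with a bound of 0.5, an equal-variance test without moderation, camera with an estimated correlation, and fry. Added after seeing the data were a fit of all 37870 rows, the ratio table without the intensity trend, and the estimated correlation without vehicle replicate 1. No pair of arrays held identical columns. The labels call the replicates biological but do not say how the cultures were made, so p-values measure the spread between these samples.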

Results

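PC-346C is a human prostate cancer cell line that responds to androgen. The cells were grown in a medium with charcoal-stripped serum, testosterone, EGF and hydrocortisone. They received 50 µM Casodex (bicalutamide, an antagonist of the androgen receptor) or only the carrier, a mixture of ethanol and DMSO. Total RNA was taken after 48 h and hybridised to a one-colour NimbleGen human expression array. Each group held 3 arrays that the labels call biological replicates. Intensities were present for 37870 transcripts, of which 14769 genes with a current symbol were compared. The median intensity per array lay between 281.1 and 292.05. Vehicle replicate 1 correlated less with the other arrays (r across transcripts of 0.935 to 0.959) than the other arrays did among themselves (0.977 to 0.992).

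The comparison of Casodex with vehicle asks which transcripts changed when the androgen receptor was blocked. More genes fell than rose. Genes of DNA replication and mitosis, androgen-induced genes and chaperones of the endoplasmic reticulum (ER) were lower with Casodex. Targets of ATF4, the transcription factor of the amino acid and integrated stress response, were higher, as were the aldo-keto reductases AKR1C1 and AKR1C2, which reduce steroids and other ketones. The calls of these 5 gene lists were lost with an estimated correlation between genes (adjusted p = 0.0994 for androgen-induced genes and 0.0816 for each of the others). In all, 217 of 14769 genes changed at a Benjamini-Hochberg adjusted p under 0.05 in limma, 25 higher and 192 lower. Of these, 189 changed at least 2-fold, 22 higher and 167 lower. The 3 Casodex values lay apart from the 3 vehicle values for all 217 genes, which passing the test itself makes likely. They did so for 3406 genes (23.1%) in total. Without any group difference the mean share over splits would be 10%. Genes move together and the share in other splits was not computed, so the excess is not a test. The median log2 change over all genes was 0.02.

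The count depended on single arrays. Without vehicle replicate 1 it was 1202 (219 higher and 983 lower), which held all 217 genes. It was 164 and 38 without vehicle replicates 2 and 3, and 20, 19 and 20 without Casodex replicates 1, 2 and 3. These smaller counts came from fits that kept vehicle replicate 1 and had 1 array fewer. A lost call is not a lost change. Over the 6 fits the log2 change ran from 1.52 to 1.69 for CHAC1 and from -4.48 to -3.52 for CENPU. Both lost their calls without any Casodex replicate, and none of the 56 named genes that passed turned its sign. BIRC5, STMN1, PCNA, MCM2, MCM7, TPX2, UHRF1, PDIA4, AKR1C1, AKR1C2, TRIB3 and SESN2 were among 17 genes past the threshold whichever array was left out. The other 5, named here after their values were seen, were H2AZ1, ASF1B, CDCA5, MPC2 and MCCC2. Of the 56 named genes that passed, 22 still passed without vehicle replicate 3, and 13 without each Casodex replicate in turn.

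**Figure D1:**
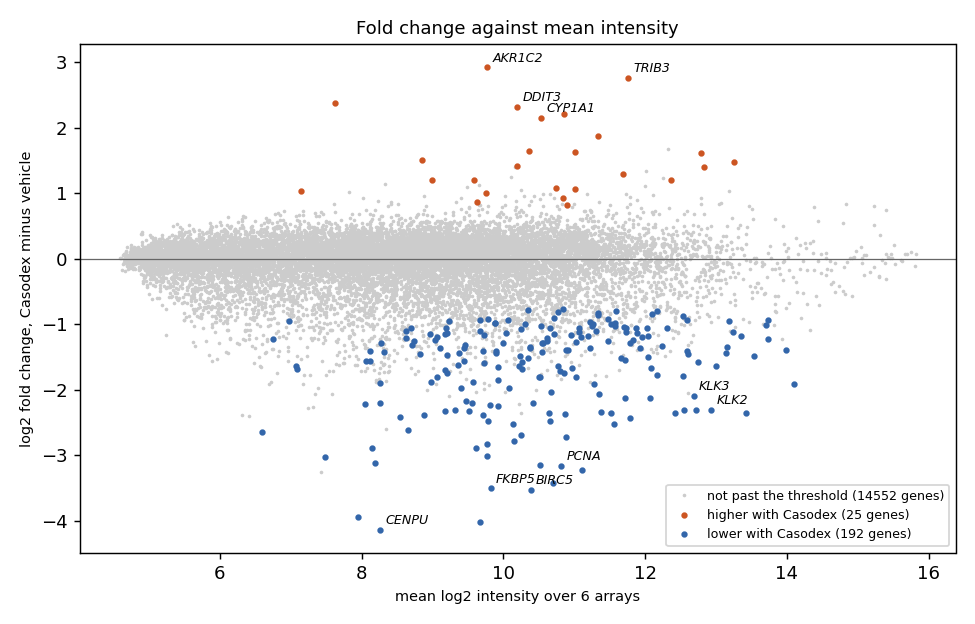
Log2 fold change (Casodex minus vehicle) against the mean log2 intensity over 6 arrays, with 1 point per gene. The 25 genes that were higher and the 192 that were lower at an adjusted p under 0.05 are coloured, and the falls reach further from 0 (CENPU, -4.14) than the rises (AKR1C2, 2.92).

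The largest fall was that of CENPU, a centromere protein, from an intensity of 1557 ± 1246 to 74.4 ± 17.8 (SD, n = 3 each), a log2 fold change of -4.14 (SE 0.50, adjusted p = 0.0151). TMSB15A, a thymosin beta that binds actin, fell too (log2 -3.95, SE 0.64). BIRC5, the mitotic and anti-apoptotic protein survivin, fell from 4559 ± 444 to 394.7 ± 39.0 (log2 -3.53, SE 0.15, adjusted p = 4.87e-04). The microtubule regulator STMN1 (-3.23), the cyclin-dependent kinase phosphatase CDKN3 (-3.02) and the replication clamp PCNA (-3.16) also fell. In CENPU and TMSB15A the vehicle arrays differed widely. Without vehicle replicate 1 their log2 changes were -3.52 and -3.11. That array was also the highest vehicle array for FKBP5, STMN1, PCNA, CCNB1, AURKA, CDKN3 and MCM2, but not for BIRC5 or CDC20. Leaving it out gave -2.74 for CCNB1, -2.62 for AURKA and -2.59 for CDKN3, but -3.77 for CDC20. TMSB15A has near-identical relatives that its probes are not certain to separate. CENPU, AURKA and FKBP5 lost their calls without each of the 3 Casodex replicates in turn. CCNB1, CDKN3 and TMSB15A also lost theirs without vehicle replicate 3, and CDC20 without Casodex replicates 2 and 3.

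On the other side, AKR1C2 had the largest rise, from 319.5 ± 37.4 to 2417 ± 194 (log2 2.92, SE 0.16, adjusted p = 8.18e-04). AKR1C1 rose from 86.8 ± 11.4 to 450.1 ± 13.4 (log2 2.38). AKR1C3, the third member on the array, differed by 0.43 (adjusted p = 0.351), but the 3 genes are close in sequence and their signals are not certain to be separate. TRIB3, a pseudokinase induced by ATF4, rose from 1338 ± 155 to 9059 ± 275 (log2 2.77, adjusted p = 8.18e-04). CYP1A1, the cytochrome P450 induced through the aryl hydrocarbon receptor, rose by 2.16 (SE 0.24), and the calcium-binding protein S100P rose 2.83-fold (SE 0.27 on the log2 scale). GTPBP2, a GTPase that acts on stalled ribosomes, rose by 1.65 (SE 0.14). These last 3 lost their calls in 2 to 5 of the 6 fits without 1 array, among them those without Casodex replicates 1 and 2.

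**Figure D2:**
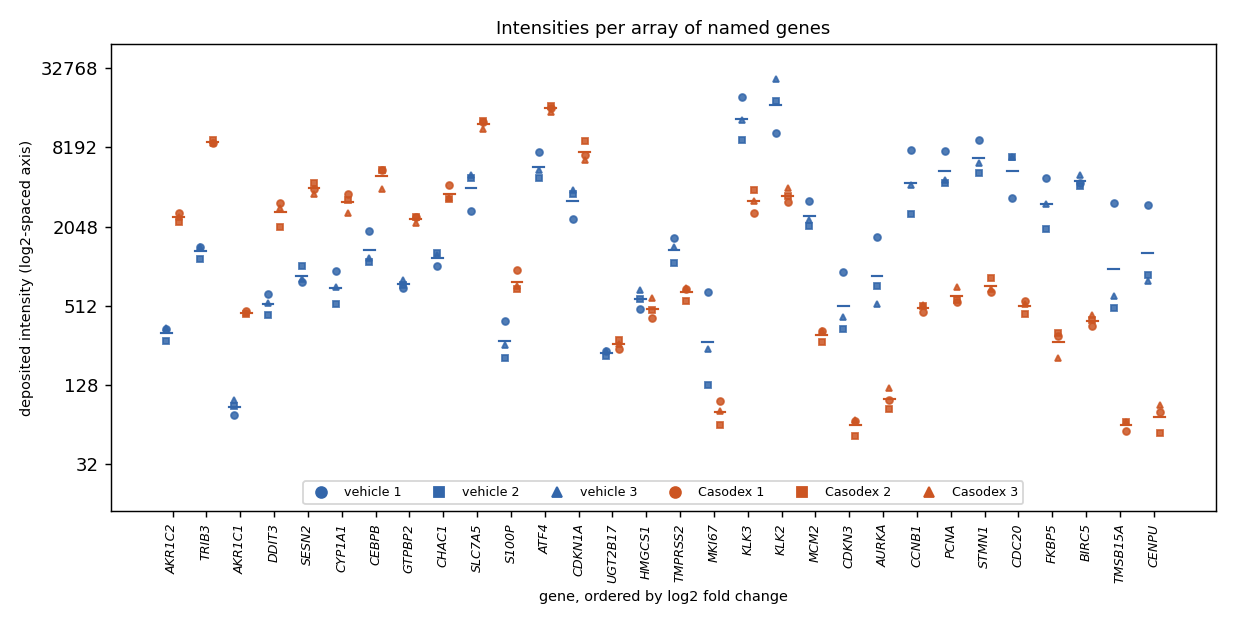
Deposited intensity of each array on a log2-spaced axis for genes with the largest rises and falls and for genes followed whatever their change, ordered by fold change; symbols are arrays and short lines are means of the log2 values. The Casodex arrays lie close together for most genes. Vehicle replicate 1 stands above the other vehicle arrays for most of the largest falls, such as CENPU, TMSB15A, CCNB1 and AURKA, but not for BIRC5 or CDC20.

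Mitotic genes were lower with Casodex. Of 38 measured genes of G2 phase and mitosis, 18 fell and none rose, and 33 fell when adjusted over the list alone. All 38 log2 changes were negative, with a median of -1.71. CDC20, an activator of the anaphase-promoting complex, fell from 5734 ± 2040 to 508.5 ± 61.6 (log2 -3.43, SE 0.29). Cyclin B1 (CCNB1, -3.16), the mitotic kinase AURKA (-3.11), the spindle protein TPX2 (-2.52) and the kinesin KIF2C (-2.38) fell, and KIF2C lost its call without each Casodex replicate in turn. MKI67, the antigen used as a proliferation marker, changed by -1.77 without passing the test (SE 0.54, adjusted p = 0.207), and by -1.14 without vehicle replicate 1 (adjusted p = 0.0107). As a set the list was lower than other genes by limma's camera (adjusted p = 3.18e-35). Its adjusted p = 0.0816 with an estimated correlation, and 1.39e-42 to 0.0219 over the other alternatives. For this list and every other that passed, the upper value came from the estimated correlation without vehicle replicate 1. At the preset correlation, fits of this list without 1 array gave at most 2.27e-31. The list stood 1.08 higher (median log2) in vehicle replicate 1 than in the other vehicle arrays, and without that array its median change was -1.53 and 31 members fell. The count was 16 and 6 without vehicle replicates 2 and 3, and 4, 2 and 2 without Casodex replicates 1, 2 and 3.

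DNA replication followed the same direction. All 39 measured S-phase genes had negative log2 changes (median -1.15). Of these, 16 fell, or 26 when adjusted over the list alone. The replicative helicase subunits MCM2 and MCM7 fell, with log2 changes of -3.01 (SE 0.20) and -2.53 (SE 0.17). PCNA fell from 5562 ± 1849 to 604.8 ± 85.9, and UHRF1, which directs maintenance of DNA methylation, from 2328 ± 173 to 336.8 ± 109.5. The list test gave an adjusted p of 4.68e-26. With an estimated correlation the adjusted p = 0.0816, and over the other alternatives it ran from 1.03e-26 to 0.0539. At the preset correlation it was at most 5.21e-22 in fits without 1 array. Vehicle replicate 1 was 0.49 above the other vehicle arrays on this list. Without it the median change was -0.94 and 23 members fell. Without vehicle replicates 2 and 3 the members that fell numbered 13 and 6, and without Casodex replicates 1, 2 and 3 they numbered 4, 4 and 5.

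Androgen-induced genes were lower in all 3 Casodex arrays. FKBP5, a co-chaperone induced by the androgen and glucocorticoid receptors, fell from 3257 ± 1444 to 273.7 ± 62.0 (log2 -3.50, SE 0.34, adjusted p = 0.00591). KLK3, which encodes prostate-specific antigen, fell from 14254 ± 5382 to 3235 ± 637 (log2 -2.09, SE 0.29, adjusted p = 0.0236), and its relative KLK2 from 18706 ± 8296 to 3532 ± 439 (log2 -2.31). KLK2 and KLK3 are similar in sequence, so their signals are not certain to be separate. ZBTB16, a zinc finger transcription factor (-1.57), and ODC1, the first enzyme of polyamine synthesis (-1.48), fell. TMPRSS2, a membrane serine protease, changed by -1.08 (adjusted p = 0.0537), short of the threshold. It passed without vehicle replicate 1 (-0.94, adjusted p = 0.00289) and without vehicle replicate 2, and in no other fit without 1 array. Of 46 measured members 8 fell and none rose, 21 fell when adjusted over the list alone, and 39 changes were negative.

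The list test of androgen-induced genes gave an adjusted p of 7.42e-14, with a median change of -0.74. Its adjusted p = 0.0994 with an estimated correlation, and 5.09e-14 to 0.0539 over the other alternatives. Fits without 1 array at the preset correlation gave at most 1.24e-12, and the upper value came from the estimated correlation without vehicle replicate 1. The androgen response score, the mean centred log2 level of the 46 genes, was -0.40 ± 0.01 with Casodex and 0.40 ± 0.29 with vehicle (SD, n = 3 each). This difference of -0.80 had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays allow. Scores were 0.73, 0.16 and 0.31 in vehicle replicates 1, 2 and 3. The genes lay 0.42 higher in vehicle replicate 1 than in the other vehicle arrays. Without it the list's median change was -0.47 and 19 members fell. Without vehicle replicates 2 and 3 there were 8 and 1, and without any of the 3 Casodex replicates 0. KLK3, ZBTB16 and ODC1 lost their calls without vehicle replicate 3 or any Casodex replicate, and KLK2 also without vehicle replicate 2. Among the 46 members, 10 also stood on another list.

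None of 17 androgen-repressed genes passed the test, alone or when adjusted over the list alone (adjusted p of the list 0.239, median log2 0.09). OPRK1, an opioid receptor, differed by 0.57 (adjusted p = 0.296) and UGT2B17, which conjugates androgens, by 0.21 (adjusted p = 0.595). Probes of the UGT2B family are not certain to separate its members. Vehicle replicate 1 was 0.24 above the other vehicle arrays on this list.

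Of 33 measured ATF4 targets 9 rose and none fell, 17 rose and 1 fell when adjusted over the list alone, and 30 changes were positive (median 0.59). DDIT3, the stress transcription factor CHOP, rose from 531.2 ± 95.2 to 2667 ± 551 (log2 2.32, SE 0.22, adjusted p = 0.00527). SESN2, a leucine sensor that restrains mTORC1, rose by 2.22, and CHAC1, which degrades glutathione, by 1.63. ATF4 itself rose from 5970 ± 1470 to 16262 ± 887 (log2 1.47), the transcription factor CEBPB by 1.88 and the amino acid transporter SLC7A5 by 1.62. The list test gave an adjusted p of 3.01e-15. Its adjusted p = 0.0816 with an estimated correlation, and 3.54e-26 to 0.0539 over the other alternatives. At the preset correlation it was at most 7.68e-12 in fits without 1 array. Vehicle replicate 1 lay 0.48 above the other vehicle arrays on this list, towards the Casodex level. Without it the median change was 0.75, and 21 members rose and 1 fell. Without vehicle replicates 2 and 3 the risers numbered 9 and 4, and without Casodex replicates 1, 2 and 3 they numbered 2, 3 and 2. DDIT3 lost its call without Casodex replicates 1 and 3, CHAC1 without any Casodex replicate, and ATF4, CEBPB and SLC7A5 also without vehicle replicate 3.

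ER chaperones moved the other way. PDIA4, a disulfide isomerase, fell from 13463 ± 1991 to 2712 ± 200 (log2 -2.30, SE 0.17, adjusted p = 0.00193). The ER protein CRELD2 (-1.80, SE 0.18), the calcium-binding chaperone calreticulin (CALR, -1.44) and PDIA6 (-1.05) also fell. In all 7 of 25 measured members fell and none rose, while 12 fell and 1 rose when adjusted over the list alone (median -0.63). For the list the adjusted p was 2.39e-08. The adjusted p = 0.0816 with an estimated correlation, and 8.47e-10 to 0.0451 over the other alternatives. Fits without 1 array at the preset correlation gave at most 1.82e-07. Vehicle replicate 1 stood 0.42 above the other vehicle arrays here, and without it the median change was -0.42, with 9 members lower and 1 higher. There were 5 and 2 without vehicle replicates 2 and 3, and 1 without each Casodex replicate, the 1 being PDIA4 as above.

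Genes of lipid synthesis were lower. In cholesterol synthesis and uptake 4 of 26 members fell, or 7 when adjusted over the list alone, with a median of -0.65. They included FDFT1 (squalene synthase, -1.80), EBP (-1.55) and FDPS (-1.03), all enzymes of the sterol pathway. HMGCS1, an early enzyme of the same pathway, changed by -0.24 (SE 0.20, adjusted p = 0.640). The list's adjusted p was 4.23e-06. With an estimated correlation its adjusted p = 0.0816, and over the other alternatives 1.24e-08 to 0.0957. At the preset correlation it was at most 7.62e-05 in fits without 1 array. Vehicle replicate 1 lay 0.43 above the other vehicle arrays on this list. Without it 10 members fell. Without vehicle replicate 2 the number was 3, and without vehicle replicate 3 or any Casodex replicate it was 0.

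In fatty acid synthesis 1 of 20 members fell, or 4 when adjusted over the list alone. It was ACLY, which makes cytosolic acetyl-CoA (log2 -1.36, SE 0.23). The desaturase FADS1 changed by -1.89 (adjusted p = 0.0512) and the elongase ELOVL5 by -1.69 (adjusted p = 0.0931). Both passed without vehicle replicate 1 (-1.47 and -1.23, adjusted p = 1.54e-04 and 2.58e-04). ELOVL5 also passed without vehicle replicate 2, and neither in the remaining fits without 1 array. The list test gave an adjusted p of 0.0105 (median -0.14). Its adjusted p = 0.0994 with an estimated correlation, and 0.00131 to 0.0957 over the other alternatives. Without vehicle replicate 2 it was 0.0517, past the threshold no longer. Vehicle replicate 1 differed from the other vehicle arrays by -0.05 on this list, and without it 6 members fell. ACLY kept its call in no other fit that left out 1 array.

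Enzymes of steroid and xenobiotic metabolism changed in few members. Of 24 NRF2 targets 3 rose (AKR1C2, AKR1C1 and the heme oxygenase HMOX1, 1.41), while 5 rose and 2 fell when adjusted over the list alone. The NRF2 list passed as a set (adjusted p = 0.0105, median 0.08). Its adjusted p = 0.142 with an estimated correlation and 3.91e-04 to 0.188 over the other alternatives, and it was 0.0552 without vehicle replicate 2. HMOX1 lost its call without vehicle replicate 3 or any Casodex replicate. Of 14 targets of the receptors AhR and PXR, CYP1A1 alone rose, also when adjusted over the list alone (list adjusted p = 0.0315, median 0.23). Here the adjusted p = 0.137 with an estimated correlation and 0.00854 to 0.114 over the other alternatives, with 0.0679 without vehicle replicate 2, 0.0608 without Casodex replicate 2 and 0.0752 without the dimmest 33.3% of genes. CYP1A1 lost its call without vehicle replicate 3 or any Casodex replicate. CYP3A5, a PXR target, differed by 0.34 (adjusted p = 0.485). Vehicle replicate 1 was 0.08 above the other vehicle arrays on the NRF2 list and 0.01 on the AhR and PXR list. Without it 6 NRF2 targets rose and 1 fell, and 1 AhR and PXR target rose.

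Among 30 genes of steroid synthesis and inactivation, AKR1C1 and AKR1C2 were the 2 that rose, and none fell (2 and 1 when adjusted over the list alone). This list missed the threshold (adjusted p = 0.0561), with 0.0461 without vehicle replicate 1, 0.0480 without Casodex replicate 1, 0.0164 without the dimmest 33.3% of genes and 0.00384 with fry. Its adjusted p = 0.142 with an estimated correlation, and 0.163 with it and without vehicle replicate 1. HSD17B4, a peroxisomal hydroxysteroid dehydrogenase, changed by -1.92 (SE 0.45, adjusted p = 0.106). It passed without vehicle replicate 1 (-1.35, adjusted p = 2.80e-04) and in no other fit without 1 array. The deviation of vehicle replicate 1 was -0.04 on this list, and without it 2 members rose and 1 fell.

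Oxidative phosphorylation subunits were lower. Of 55 measured subunits 52 had negative changes (median -0.51), 4 fell and 11 fell when adjusted over the list alone. The 4 belong to complex I of the respiratory chain: NDUFS5 (-1.21), NDUFAB1 (-1.06), NDUFS6 (-0.88) and NDUFC1 (-0.85). The list's adjusted p was 2.94e-12. Its adjusted p = 0.0994 with an estimated correlation, and 1.51e-12 to 0.110 over the other alternatives. Fits without 1 array at the preset correlation gave at most 8.98e-10. The subunits lay 0.33 higher in vehicle replicate 1 than in the other vehicle arrays. Without it 13 members fell, and without any other array 0.

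In glycolysis and the hypoxia response 2 of 30 genes fell and 1 rose (5 and 1 when adjusted over the list alone). Lactate dehydrogenase A (LDHA) fell from 5502 ± 3223 to 738.6 ± 63.7 (log2 -2.72, SE 0.41), and the glycolytic enzyme PGAM1 fell as well (-1.33). LDHA stood at 8922 in vehicle replicate 1, against 2521 and 5064 in vehicle replicates 2 and 3. Its change without vehicle replicate 1 was -2.28. VEGFA, the angiogenic growth factor, rose by 1.09 (SE 0.19). The list was lower as a set (adjusted p = 2.80e-04, median -0.31). With an estimated correlation the adjusted p = 0.142, and over the other alternatives 2.13e-04 to 0.110. In fits without 1 array at the preset correlation the list gave at most 0.00157. Its genes were 0.32 higher in vehicle replicate 1 than in the other vehicle arrays. Without that array 7 members fell and 1 rose, without vehicle replicate 2 there were 2 and 0, and without vehicle replicate 3 or any Casodex replicate none passed.

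Ribosome biogenesis genes and MYC targets fell in 4 of 28 cases, or 10 when adjusted over the list alone, and 26 changes were negative (median -0.49). Examples were the nucleolar proteins NCL (-1.41), DKC1 (-1.40) and MRTO4 (-1.15). The adjusted p of the list was 7.03e-10. Its adjusted p = 0.0816 with an estimated correlation, and 4.45e-10 to 0.0451 over the other alternatives. At the preset correlation it was at most 3.03e-08 in fits without 1 array. In vehicle replicate 1 the list lay 0.32 above the other vehicle arrays. Without it 13 members fell and 1 rose, without vehicle replicate 2 the falls numbered 5, and without vehicle replicate 3 or any Casodex replicate 0.

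Glucocorticoid-induced genes fell in 2 of 15 cases (4 when adjusted over the list alone). These were FKBP5 and ZBTB16, which are also on the androgen-induced list. KLF9 changed by -0.79 (adjusted p = 0.134) and NFKBIA by -0.69 (adjusted p = 0.142). Both passed without vehicle replicate 1 (-0.61 each, adjusted p = 0.0468 and 0.0286), and in no other fit without 1 array. The list passed with an adjusted p of 0.0276 (median -0.15). Its adjusted p = 0.136 with an estimated correlation and 0.00408 to 0.109 over the other alternatives, with 0.0826 without vehicle replicate 2, 0.0853 without vehicle replicate 3 and 0.0523 with the replicate number as a block. In vehicle replicate 1 these genes lay 0.15 above the other vehicle arrays. Without it 4 members fell, without vehicle replicate 3 there was 1, and without any Casodex replicate 0.

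**Figure D3:**
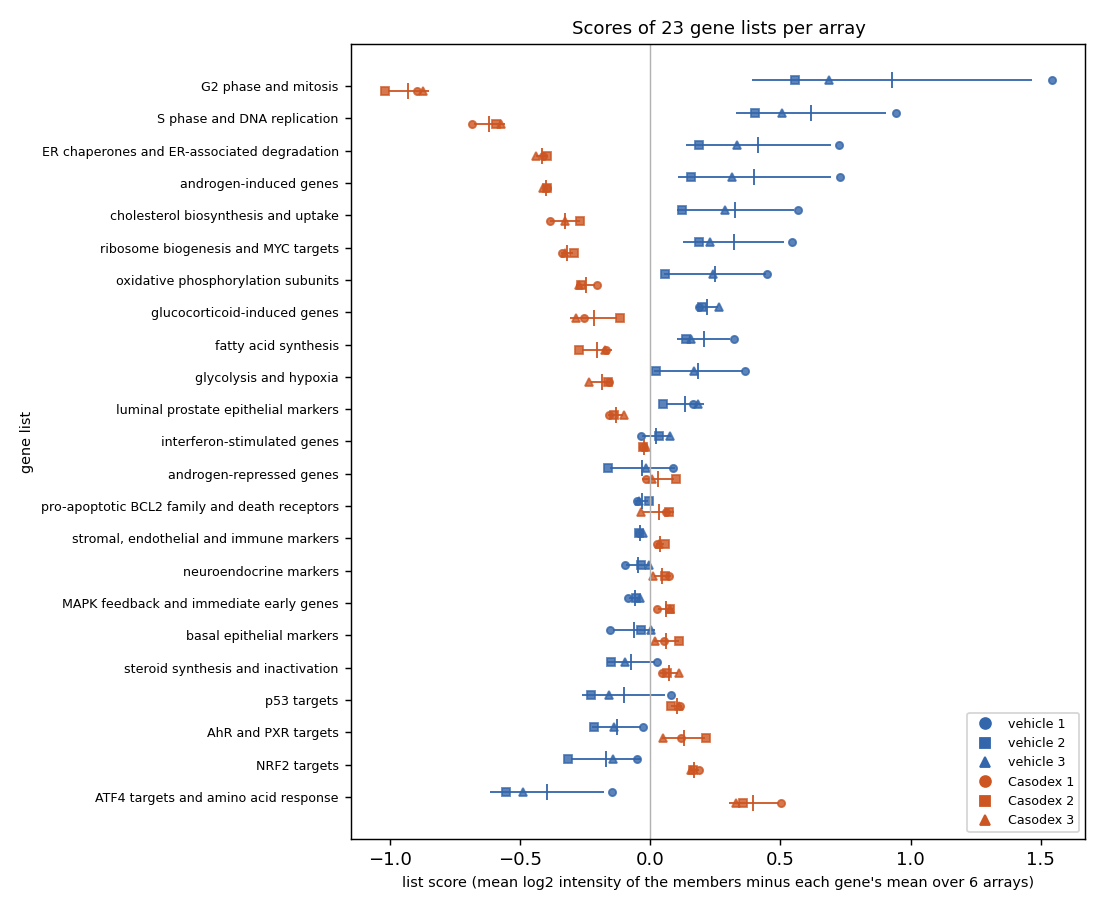
Score of each of 23 gene lists per array (mean log2 intensity of the members minus each gene's mean over 6 arrays), with group means (ticks) and SD (bars), n = 3 arrays per group. The groups stand furthest apart for G2 phase and mitosis, where vehicle replicate 1 also lies well above the other vehicle arrays.

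In total 13 of the 23 lists passed in camera, 3 higher (ATF4, NRF2, and AhR and PXR targets) and 10 lower. None passed with an estimated correlation, where the lowest adjusted p = 0.0816 and 9 lists had an unadjusted p under 0.05. With fry, which asks only whether a list's genes move one way, 18 passed. The 5 that fry added were steroid metabolism (adjusted p = 0.00384), MAPK feedback (0.00384), luminal markers (0.00421), stromal, endothelial and immune markers (0.0248) and neuroendocrine markers (0.0332).

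The remaining lists did not pass in camera with all arrays as deposited. Of 27 p53 targets SESN2 rose, or 2 genes when adjusted over the list alone. SESN2 is also on the ATF4 list, and is 1 of 5 p53 targets that stand on another list. CDKN1A, the cell cycle inhibitor p21, went from 3269 ± 826 to 7615 ± 1402 (log2 1.24, SE 0.24, adjusted p = 0.0601), and its other transcript differed by 0.51. CDKN1A passed without vehicle replicate 1 (1.01, adjusted p = 8.50e-04) and in no other fit without 1 array. The p53 list's adjusted p was 0.0561. It passed with quantile normalization (0.0389), median scaling (0.0436), cyclic loess (0.0234), array weights (0.00419) and without the dimmest 33.3% of genes (0.0111). The list's median change was 0.05 as deposited, and 0.03, 0.02 and -0.0051 with quantile, median and cyclic loess scaling. The adjusted p was 2.82e-04 without vehicle replicate 1, when 5 members rose, and 0.0486 without Casodex replicate 2. Its adjusted p = 0.176 with an estimated correlation, and 0.0741 with it and without vehicle replicate 1. Vehicle replicate 1 lay 0.30 above the other vehicle arrays on this list. Among 21 pro-apoptotic genes and death receptors none passed, and 1 fell when adjusted over the list alone (list adjusted p = 0.317). BBC3 (PUMA) differed by 0.59 (adjusted p = 0.152) and BID by -0.72 (adjusted p = 0.0610). Both passed without vehicle replicate 1 (0.53 and -0.71, adjusted p = 0.0422 and 0.00686), and in no other fit without 1 array. Vehicle replicate 1 deviated by -0.08 here, and without it 2 members rose and 2 fell.

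Of 22 genes of MAPK feedback and the immediate early response, IER3 rose (1.07) and cyclin D1 (CCND1) fell (-1.06), or 3 and 1 when adjusted over the list alone (list adjusted p = 0.0695). The deviation of vehicle replicate 1 was -0.05 on it. Without that array 2 members rose and 1 fell, and without any other array none passed. Of 29 interferon-stimulated genes B2M, the light chain of MHC class I, fell (-1.80, SE 0.27), also when adjusted over the list alone. It lost its call without vehicle replicate 3 or any Casodex replicate. The interferon list's median was 0.04 and its mean -0.05, and its test pointed up (adjusted p = 0.894), so their signs disagree. Vehicle replicate 1 deviated by -0.01 on it.

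Markers of cell identity moved little as sets. Of 24 luminal prostate epithelial markers KLK3 and the keratin KRT18 (-1.05, SE 0.15) fell, or 4 when adjusted over the list alone, with a median of -0.02 (list adjusted p = 0.218). Without vehicle replicate 1 the luminal list passed (adjusted p = 0.0462), with 7 members lower and 1 higher, but not with an estimated correlation and without that array (adjusted p = 0.172). KRT18 lost its call without vehicle replicate 3 or any Casodex replicate. None of 21 neuroendocrine markers, 20 basal markers or 24 stromal, endothelial and immune markers passed, also when adjusted over each list alone. The adjusted p was 0.0695 for each of these 3 lists, with medians of 0.14, 0.12 and 0.15. Vehicle replicate 1 deviated by -0.07, -0.16 and -0.07 on them and by -0.04 on the luminal list, and without it 1 neuroendocrine marker fell. The adjusted p of the basal list was 0.0294 without Casodex replicate 3, and 0.142 with an estimated correlation over all arrays. Calcitonin (CALCA) differed by 0.45 (adjusted p = 0.249) and the basal marker CAV1 by 0.52 (adjusted p = 0.208).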

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

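The list tests, the estimated correlation and the fits without 1 array were chosen before the data were seen. The explanations weighed here for vehicle replicate 1, the cell cycle lists and the ATF4 and ER lists were chosen after the patterns were seen. The expected outcome was written before the result only for the correlation of transcripts of the same gene and for the splits of the arrays.

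Among the 21133 rows without a current symbol, which the comparison of genes did not use, 26 (0.12%) changed with Casodex in a fit of all rows, 3 higher and 23 lower. In the same fit 182 of 16737 rows with a symbol changed. Several are described as models similar to genes of the cell cycle, histones, tubulins or small nuclear ribonucleoproteins, but whether such rows are more frequent among the 26 was not tested. They include a model similar to histone H2A.Z (-1.75), a model similar to an alpha tubulin (-2.41), the condensin II subunit D3 (-2.15, on the androgen-induced list but not measured under its symbol) and the protein MAC30 (-2.19). A second transcript described as activating transcription factor 3 rose by 1.59, while the row used for ATF3 differed by 1.40 (adjusted p = 0.148).

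Vehicle replicate 1 stood apart. Against the mean of the other vehicle arrays, 1638 of 14769 genes were higher by at least 1 on the log2 scale and 438 lower, with an SD over genes of 0.69 (0.24 between the other vehicle arrays). A Casodex array under a vehicle label is argued against. On an axis from the other vehicle arrays (0) to the Casodex arrays (1) over 1202 genes, vehicle replicate 1 lay at -0.21. These genes were called in the fit without it. The other arrays' distances from their group's mean, no more than 0.04, were therefore small by choice and give no yardstick. RNA of cells without luminal markers as the cause of the 438 lower genes is argued against too. Dilution to that degree would need at least as much other RNA as the cells' own, and would lower their markers alike. The 24 luminal markers had a median deviation of -0.038 (spread 0.76). A smaller share, other cells with the same markers and the 1638 higher genes are not covered. KLK3, a marker that androgen induces, was higher in that array (20022, against 9367 and 13374) and such genes could mask a drop. The androgen-induced KLK2, not among these markers, was lower (10471, against 18587 and 27061). A difference in that culture's own transcripts stays open: the deviations of 671 pairs of transcripts of the same gene correlated at r = 0.75 across genes (95% bootstrap interval 0.687 to 0.809), against 0.73 (0.677 to 0.776) for the Casodex changes, but such pairs can share probes, so a technical cause that follows sequence could do the same.

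The cell cycle genes were lower in Casodex and highest in vehicle replicate 1. That array alone as the cause is argued against, since without it the median change of the members of both lists was -1.19, with a spread over the root of their number of 0.12. That spread is over genes, which are correlated (estimated at 0.29 for S phase and 0.40 for G2 phase and mitosis), and does not measure differences between cultures. The same holds for the spreads of the ATF4 and ER lists below. An effect of Casodex is the candidate explanation that the design names, and a difference between cultures in cell density or growth was not tested.

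Of 33 ATF4 targets 9 rose, and of 25 ER chaperones and related genes 7 fell, calls of lists that were lost with an estimated correlation (adjusted p = 0.0816 for each). The deviation of vehicle replicate 1 was positive on both lists, and without it the ATF4 median was 0.75 (spread over the root of the number 0.11), so that array alone is argued against as the cause. An unfolded protein response that raises both lists is argued against by the chaperones' median of -0.63 (0.19, and -0.42 without vehicle replicate 1). A stress response through ATF4 without the chaperones may be at work, which stays a hypothesis because no protein was measured. With 10 splits of the arrays into 3 and 3, no share under 0.05 can be had. The real split, 1 of 10, gave 217 genes and the highest other split 0, and for lists the real split, again 1 of 10, gave 13 and the highest other 9.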

How the results depend on the processing

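The series value table without a trend, the estimated correlation without vehicle replicate 1 and the fit of all rows were added after the data were seen. The count of genes changed by Casodex, 217, lay between 162 and 318 with other normalizations, without the dimmest 33.3% of genes, with the mean of rows, without trend, with robust eBayes, at a 2-fold threshold and over all rows (208). It was 2153 with array weights. These were 0.139, 1.00 and 5.17 for vehicle replicates 1, 2 and 3, so the vehicle side rested largely on replicate 3. The count was 39 with treat and 8 with the equal-variance test. In the series value table, which holds ratios, so that its trend follows centred means, it was 480, and without trend 215. Leaving out each array gave 19 to 1202. The replicate block gave 76 genes, 72 of them among the 217. After each gene's group mean was subtracted, same-numbered arrays correlated at 0.126, 0.151 and -0.117. Of the 3 vehicle arrays, 2 correlated best with the Casodex array of their own number. With so few arrays this cannot settle whether the numbers pair samples. Lists past the threshold numbered 13, and 14 with quantile, median and cyclic loess scaling and with array weights, each of which added the p53 targets. Without the dimmest 33.3% there were also 14, with p53 targets and steroid metabolism gained and AhR and PXR targets lost. There were 9 to 16 without 1 array, 12 with the block, 18 with fry, 0 with an estimated correlation and 3 with it and without vehicle replicate 1 (G2 phase and mitosis, ER chaperones, ribosome biogenesis). The difference in androgen score (Casodex minus vehicle) ran from -0.93 to -0.64. The ratio table gave no lists, score or genes, robust eBayes no list test, and normexp was not run on corrected values. Of the 102 named genes, 56 passed, and none of these and no list past the threshold turned in any setting; calls were lost in 228 of their 839 gene values and gained in 54 of the others. Values that turned had not passed, such as KRT15 with -0.028 under array weights. The interferon list pointed down with quantile normalization (adjusted p 0.932), cyclic loess (0.832), array weights (0.638), fry (0.526) and the estimated correlation without vehicle replicate 1 (0.667), and without vehicle replicate 1, Casodex replicate 1 or Casodex replicate 3, with 0.654 to 0.995 over the fits without 1 array. Other causes were not tested. Dim genes limit the folds, since intensities end near 21.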

Other observations

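The gene families here were picked by symbol after the data were seen, and all 16 were tested with camera. Each family except that of iron and heme held every measured gene with a matching symbol. Such a family can include relatives outside the class it is named for. The iron and heme family was instead a set of 7 genes named one by one after the data were seen. The tubulin symbols also match gamma-tubulin complex proteins. SNRP and LSM symbols also match proteins outside the core of the splicing particles, and EIF symbols kinases and binding proteins of translation initiation factors. All 8 subunits of the CCT chaperonin, which folds actin and tubulin, had negative changes (median -1.18), and CCT2 (-1.24) and CCT3 (-0.80) fell. The 22 genes with SNRP and LSM symbols include core proteins of the splicing ribonucleoproteins. Of the 22, SNRPG (-1.57), LSM3 (-1.44), LSM6 (-1.36) and SNRPE (-1.19) fell, and 20 changes were negative (median -0.72). Mitochondrial ribosomal proteins were negative in 68 of 73 cases (median -0.42), with falls of MRPS17 (-1.03), MRPL51 (-1.03) and MRPL18 (-0.94). Proteasome subunits were negative in 33 of 38 cases (median -0.59), where PSMA1 fell (-1.47). The tubulins TUBA1B (-1.91), TUBA1C (-1.40) and TUBB4B (-1.35) fell. The members of these 5 families that fell numbered 7, 12, 21, 12 and 8 without vehicle replicate 1, and 0, 4, 1, 2 and 2 without vehicle replicate 2, and none fell without vehicle replicate 3 or any Casodex replicate. Medians of these families kept their sign under quantile, median and loess scaling.

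The adjusted p was 7.54e-08 for the chaperonin, 2.47e-09 for the SNRP and LSM family, 7.05e-13 for the mitochondrial ribosome, 1.91e-10 for the proteasome and 1.36e-04 for the tubulin family. With an estimated correlation these calls were lost, at 0.1605, 0.0908, 0.144, 0.144 and 0.0908. Splicing factors of the hnRNP and SR kinds (median -0.83, 28 of 29 negative) and genes with EIF symbols (-0.35, 39 of 50 negative) also passed. With an estimated correlation their adjusted p = 0.260 and 0.404. Vehicle replicate 1 was higher by 1.23 and 0.62 on these 2 families, and without it their medians were -0.40 and -0.11. All 9 metallothioneins had positive changes (median 0.19, adjusted p = 0.0275, 0.173 with an estimated correlation and 0.102 without vehicle replicate 1). In all 9 of the 16 families passed and none with an estimated correlation, where the lowest adjusted p = 0.0908. Vehicle replicate 1 stood above the other vehicle arrays on the chaperonin, SNRP and LSM, mitochondrial ribosome, proteasome and tubulin families, by 1.21, 0.22, 0.41, 0.51 and 0.08. Without it their medians were -0.84, -0.63, -0.34, -0.43 and -0.31. Cytosolic ribosomal proteins did not pass (median -0.07 over 81 genes, adjusted p = 0.0543), and their median turned to 0.02 with quantile and 0.01 with loess scaling. They passed without vehicle replicate 2 (0.00633, or 0.245 with an estimated correlation) and without Casodex replicate 1 (0.0234, or 0.448). Nor did mitochondrial tRNA synthetases (-0.24, adjusted p = 0.0505), V-ATPase subunits (-0.12, adjusted p = 0.497) or cytosolic tRNA synthetases (0.16, adjusted p = 0.318). Mitochondrial tRNA synthetases passed without vehicle replicate 2 (0.0312), vehicle replicate 3 (0.0308) or Casodex replicate 3 (0.0395), and with an estimated correlation in none of these fits (0.310, 0.407 and 0.467). Without vehicle replicate 1 the cytosolic ones had a median of 0.33, 7 members higher and 2 lower, with an adjusted p of 0.00104 that was 0.333 with an estimated correlation.

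Of 72 histone genes H2AX (-2.35), H2AZ1 (-2.36) and H4C3 (-2.43) fell, while the family's median was near 0 (-0.0039, adjusted p = 0.207). Without vehicle replicate 1, 8 histone genes fell and 1 rose, without Casodex replicates 1 and 2 the falls numbered 2 each, and without Casodex replicate 3 there was 1. Near-identical histone genes are not certain to be separated by their probes. Among 7 genes of iron and heme HMOX1 rose, a call lost without vehicle replicate 3 or any Casodex replicate, and FTH1, the ferritin heavy chain, differed by 0.83 (adjusted p = 0.292), or 1.13 without vehicle replicate 1 (adjusted p = 7.08e-04). The family passed in camera (adjusted p = 0.0275), but not with an estimated correlation (0.249). Its members were named one by one after the data were seen, so its test gives no independent support. Without vehicle replicate 1 the camera value was 8.41e-04. The call was lost without vehicle replicates 2 (0.0571) and 3 (0.105) and Casodex replicates 1 (0.0545) and 2 (0.0616).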
